A study of Homo sapiens with 8 samples.

How the data were processed

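RNA was measured in 8 samples of retinal pigmented epithelium (RPE) made by spontaneous differentiation of H9, an established human embryonic stem cell line. Per the labels, the cells came from 4 separate enrichments of RPE, numbered 20, 21, 26 and 27, and each enrichment gave a culture kept in 10 µM Y-27632, an inhibitor of the kinases ROCK1 and ROCK2, and a control culture given water. The cells were seeded at 25000 per square cm on Matrigel in XVIVO-10 medium and collected at passage 5, on day 2 after plating. Per the labels' protocols, total RNA was extracted with QIAzol and a miRNeasy kit, and 250 ng was labelled with an Agilent Low Input Quick Amp kit without spike-ins. Both cultures of an enrichment were hybridised to a single array, the control always labelled with Cy3 and the Y-27632 culture always with Cy5, and the dyes were read as separate channels. No dyes were swapped, so a bias of a probe towards one dye could not be separated from the treatment by the design.

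Each of the 4 arrays had 45220 spots, of which 1844 were control spots, and 41000 probes, a probe having at most 10 replicate spots. The deposited scanner values were intensities on a linear scale, per the file headers: a raw median spot intensity, a background and a net intensity for each channel. The raw values were whole numbers in 100% of spots, and the background was a single value per channel. From the values, the net Cy3 intensity equalled raw minus background for 100% of spots. The net Cy5 intensity was further multiplied by a factor that varied smoothly with brightness, with a median of 1.74, 1.53, 1.76 and 2.06 on arrays 20, 21, 26 and 27. The scanner, the image software and its settings were not given in the sources used here. A further table held linear intensities normalized by the authors, with a median of 8.145 in every column and a lowest value of 1.34. Set against the net intensities on a log2 scale, its columns correlated at 0.981 to 0.993 across probes, which are not independent replicates. The scale was therefore known from the values, while the steps that led to it were not given in the sources used here.

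The main values were computed from the raw intensities and backgrounds with limma 3.58.1 in R 4.3.3 (tables read with the data.table package, version 1.17.8). Background was corrected with normexp and an offset of 50, arrays were normalized within by loess with control spots at weight 0 and between by the Aquantile method, and the ratios were split back into channels. Replicate spots were averaged. No flag for spots above background was used, so a probe was tested if its raw intensity exceeded the 95th percentile of the 153 negative control spots in at least 4 of the 8 channels, which 24623 probes did. Probes were named through the platform's annotation: 29244 had 1 gene symbol, 84 had several and were not named, and 11672 had none. Of the single-symbol probes, 29203 matched a RefSeq table of assembly GRCh38.p14 by gene identifier and 0 were renamed. A gene was represented by its brightest tested probe, which left 12545 genes. Some probes of a gene disagreed with the one used: for ACTB, ACTG1, BMP7, CYP51A1, EZR, FZD4, JUNB, KRT8, RAB32, TJP1 and ZEB2 at least 1 other tested probe had the opposite sign. No genome was used, so no coordinates are given.

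Log2 intensities of the 8 channels were fitted with lmFit and eBayes, with the array as a fixed block and Y-27632 minus control as the contrast, which left 3 residual degrees of freedom and a prior of 3.11. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. An intensity is in log2 units throughout, and a log2 change of a dim gene is shrunk by the offset. The number of arrays limits the precision. The p-values measure the spread between 4 enrichments of a single cell line. The enrichment numbers come from the labels, which also place both samples of a number on a shared array. The samples were therefore treated as pairs, as planned. Deviations from the group means correlated within enrichments at 0.80, 0.58, 0.66 and 0.84 (20, 21, 26, 27), against at most 0.05 between enrichments. Both samples of an enrichment were channels of the same spots, which can alone give such a correlation. Subtracting means of 4 samples also lowers the correlations between enrichments. These values therefore do not show that the cultures of an enrichment were alike.

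22 gene lists were fixed and tested, of which 21 are described: RPE function and visual cycle, pigmentation, RPE and eye-field transcription factors, mesenchymal and extracellular matrix, epithelial junctions and keratins, TGF-beta and BMP signalling, actin cytoskeleton and SRF targets, YAP and TAZ targets, cell cycle, cell cycle arrest and senescence, WNT signalling, interferon response, hypoxia and glycolysis, cholesterol synthesis, immediate-early and stress, and 6 lists of markers of other cell types. Lists were tested against all other genes with camera at a preset correlation of 0.01, and again with the correlation estimated, and with fry, which asks whether a list's genes move one way on balance. Each was adjusted by Benjamini-Hochberg over the 22 lists. The genes named are the 10 largest rises and the 10 largest falls among called genes that moved one way on all 4 arrays, up to 2 members of each list per direction with the smallest adjusted p, and a fixed set: RPE65, BEST1, RLBP1, TYR, PMEL, MITF, OTX2, CDH1, VIM, ACTA2, TGFB2, CCN2, MKI67, ROCK1 and ROCK2. Where 5 or fewer members of a list moved one way, those beyond this rule are also named, chosen after their values were seen. A further list, the genes named through it and a gene of the fixed set are not reported here. RPE65 had a probe that was above background in 0 of the 8 channels and was not tested. The grouping, the design, the lists, the naming rule and the alternatives were chosen before the data were examined.

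The steps were tested on simulated data for the comparison of Y-27632 with control, in which 200 of 12545 genes were changed. Of 50 genes at each size, 38% were recovered at a log2 change of 0.5, 88% at 1, and 100% at 2 and at 3, with the right sign in 50 of 50 at each size. The changed genes were drawn from those above background in all control channels, so recovery of dimmer genes was not tested. False calls were 12 of 175 (6.86%). The simulated dye difference depended on brightness and array alone, so false calls from dye bias of single probes were not tested. Among 100 unshifted lists 0 were called, and a list of 30 genes shifted by 0.5 had a camera adjusted p of 2.14e-31. The simulated noise was independent between probes, so this does not test false calls of lists whose genes move together. In the data the correlation estimated for the cell cycle list was 0.85. The alternatives were the net intensities, no background subtraction, quantile normalization of single channels, scaling to the 75th percentile, median centring in place of loess, the authors' normalized values, no filter or all 8 channels above background, no block or a random block for arrays, a trended variance prior, the mean of a gene's probes, stricter thresholds, an estimated correlation in the list test and leaving out each enrichment. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.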

Results

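Gene expression was measured on 4 two-colour arrays in RPE cells derived from H9 embryonic stem cells, with 4 samples kept in 10 µM Y-27632 and 4 water controls, a pair from each of enrichments 20, 21, 26 and 27. The study asked how inhibition of the kinases ROCK1 and ROCK2 affects RPE cells that are passaged repeatedly, and the arrays compare both cultures at passage 5, on day 2 after plating. Signal stood little above background for most probes. The median raw probe intensity in control and Y-27632 channels was 339 and 381 on array 20, 334 and 386 on array 21, 357 and 381 on array 26 and 361 and 383 on array 27, over backgrounds of 297 to 314 in the control channels and 357 to 362 in the Y-27632 channels. The share of probes above the negative control spots was 67.8% and 65.1% on array 20, 62.8% and 62.0% on array 21, 58.0% and 57.1% on array 26, and 46.7% and 45.1% on array 27. Dye and treatment were the same split of the channels, so every difference given here is also a difference between Cy5 and Cy3.

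Cells kept in Y-27632 had higher levels of cell cycle genes and of several genes of RPE function, and lower levels of genes of the extracellular matrix, of several genes of TGF-beta and BMP signalling and of genes of hypoxia and glycolysis. Camera called these 5 lists (Benjamini-Hochberg), but each call was lost, at adjusted p = 0.577 with an estimated correlation. That correlation was estimated from 3 residual degrees of freedom, and this setting called no list. The endothelium list, with 0 of 4 members past the test, had the same camera adjusted p of 0.577. Benjamini-Hochberg adjustment can give lists with different p a shared value, so this tie does not show equal evidence. The 5 calls rest on the preset correlation of 0.01. Under median centring the TGF-beta list was not called (camera, Benjamini-Hochberg adjusted p = 0.173), and the RPE function list was at -0.07, yet 0.33 above the median of all genes and called (0.000232). COL8A2, which encodes a collagen of basement membranes, was 7.99-fold higher (log2 change 3.0, SE 0.267, n = 4 pairs), and TYR, the rate-limiting enzyme of melanin synthesis, was 4.88-fold higher (2.29, SE 0.575), though camera did not call its pigmentation list (Benjamini-Hochberg adjusted p = 0.113). ITGA11, a subunit of a collagen receptor, fell by 3.68 on the log2 scale (SE 0.189), a 12.8-fold difference, and LUM, a proteoglycan that binds collagen fibrils, fell by 3.42 (SE 0.307). Other probes of TYR and ITGA11 changed less. Of 31 measured cell cycle genes, 30 were higher, and of 27 mesenchymal and matrix genes, 17 were lower. Of 12545 genes tested with limma, 1606 were higher and 2244 lower with Y-27632 at a Benjamini-Hochberg adjusted p under 0.05, of which 195 and 184 changed at least 2-fold. Without the block for arrays the counts were 380 higher and 562 lower. Without enrichment 20 they were 1016 and 1421, without 26 they were 936 and 1351, and without 27 they were 583 and 889. The higher genes made up 41.7% of the calls, against 31.6% without background subtraction and 4.36% when median centring replaced loess, a scaling that placed the median of all genes at -0.41 in place of -0.02. Of the 96 named genes past the test, the change was over 1.5 times smaller or reversed for 56 without background subtraction, 30 under median centring and 21 as the mean of a gene's probes. It was over 1.5 times larger for 24 under median centring, 21 in the authors' values, 16 with net intensities and 15 at their 75th percentile. Of all genes tested, 6563 (52.3%) moved one way on all 4 arrays, where chance gives 12.5%. A constant dye bias of a probe would also move a gene one way on all 4 arrays. This share therefore does not separate treatment from dye.

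After COL8A2 (limma, Benjamini-Hochberg adjusted p = 0.00337) among the 10 largest rises came the chemokine CXCL14 (5.13-fold, log2 2.36, SE 0.145, adjusted p = 0.00254 by limma with Benjamini-Hochberg adjustment) and the serpin SERPINE3 (4.99-fold, log2 2.32). The muscle ubiquitin ligase TRIM63 rose 4.32-fold, RARRES2, which encodes the secreted protein chemerin, 4.15-fold, and ASPM, a protein of the mitotic spindle, 4.07-fold. SMPD3, a neutral sphingomyelinase, rose 3.89-fold, LIMCH1, an actin-associated protein that activates non-muscle myosin, 3.80-fold, and the membrane-bound carbonic anhydrase CA14 3.76-fold. Other probes were at 0.68 for LIMCH1, 1.25 for ASPM, and 2.02 and 0.65 for TYR on the log2 scale. The means of their probes were 1.30, 1.64 and 1.65. The mean log2 level of CXCL14 was 11.70 ± 0.40 (SD, n = 4) with Y-27632 and 9.34 ± 0.11 in controls, while TYR stood at 10.26 ± 0.22 and 7.98 ± 1.45. TYR was called at an adjusted p = 0.0303 by limma with Benjamini-Hochberg adjustment and had log2 ratios of 0.66, 1.26, 4.24 and 2.98 on arrays 20, 21, 26 and 27. It missed the threshold without enrichment 26 (log2 1.63, limma's Benjamini-Hochberg adjusted p = 0.0577), without 27 (2.05, 0.118), without the block (0.0572), with no filter (0.0711) and without background subtraction (1.33, 0.0632).

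The 10 largest falls were led by ITGA11, from 11.44 ± 0.65 (SD, n = 4) in controls to 7.76 ± 0.36 with Y-27632 (adjusted p = 0.00254, limma with Benjamini-Hochberg adjustment). Another probe of ITGA11 was at -1.84, and the mean of its probes at -2.76. The protease-activated receptor F2RL2 fell by 3.03 on the log2 scale (SE 0.141), but another probe was at -0.40 and the mean of its probes at -1.71. The cell adhesion protein AMIGO2 fell by 3.01 (SE 0.288). The teneurin TENM2 fell by 2.28, while CDKN2B, an inhibitor of the kinases that start the cell cycle, fell by 2.28, with another probe at -0.18 and the mean of its probes at -1.23. FBN1, the main protein of microfibrils, fell by 2.26, WNT5A, a ligand of non-canonical WNT signalling, fell by 2.23, LOX, which cross-links collagen and elastin, fell by 2.01, and ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell by 2.00. All 20 genes of both groups moved one way on the 4 arrays, as the rule for naming them required. Of these, TYR alone lost its call when an enrichment or the block was left out.

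**Figure D1:**
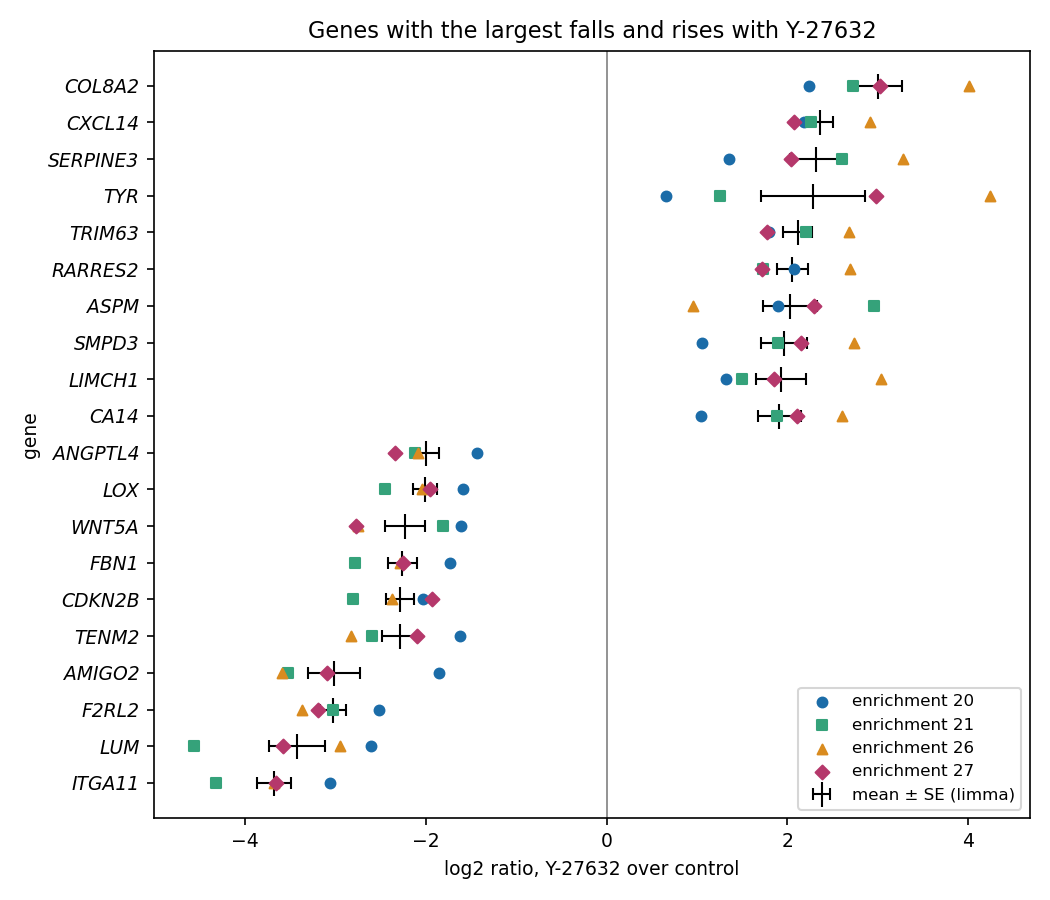
Log2 ratio of Y-27632 over control (x axis) for the 10 genes with the largest rises and the 10 with the largest falls (y axis), with a symbol per enrichment and the mean ± SE from limma as black bars. The falls reach -3.68 for ITGA11, the rises reach 3.0 for COL8A2, and the ratios of TYR spread from 0.66 to 4.24.

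Genes of the cell cycle rose together. Of 31 measured members, 30 were higher, 0 were lower and 1 did not pass, and 31 were higher when adjusted over the list alone. The mean log2 change was 1.08, with means of 1.0, 1.83, 0.57 and 0.92 on arrays 20, 21, 26 and 27. PLK1, a kinase of mitotic entry, rose by 1.33 on the log2 scale (SE 0.136, limma, Benjamini-Hochberg adjusted p = 0.00374), and NUSAP1, a protein of the spindle, rose by 0.96 (SE 0.101, adjusted p = 0.00387). MKI67, a marker of dividing cells, rose by 0.56 (SE 0.132, limma, Benjamini-Hochberg adjusted p = 0.0253), above background in 4 Y-27632 and 3 control channels. AURKB, a kinase of chromosome segregation chosen after its value was seen, was the member that did not pass, at 0.30 (limma, Benjamini-Hochberg adjusted p = 0.0508), though with 6 other settings it passed, such as net intensities (0.72, adjusted p = 0.0245). The list stood above other genes by camera (Benjamini-Hochberg adjusted p over 22 lists = 5.61e-14), with adjusted p = 0.577 with an estimated correlation, and fry gave an adjusted p of 0.0389. MKI67 missed the threshold without enrichment 20, 26 or 27, at log2 values of 0.59, 0.59 and 0.65 and limma's Benjamini-Hochberg adjusted p of 0.0638, 0.0625 and 0.0538, without the block (0.0531), with no filter (0.0513) and without background subtraction (0.12, 0.0809). The cell cycle mean was 0.65 without background subtraction and 0.57 under median centring. MKI67 ran from 0.12 to 1.61 over the settings.

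Among 27 measured genes of RPE function and the visual cycle, 11 were higher, 3 were lower and 13 did not pass. Adjusted over the list alone, 12 were higher and 3 lower. RLBP1, the retinal-binding protein of the visual cycle, rose from 7.79 ± 0.65 to 9.51 ± 0.58 (log2 change 1.72, SE 0.365, limma, Benjamini-Hochberg adjusted p = 0.0190). The lactate transporter SLC16A8 rose by 0.88 (limma, Benjamini-Hochberg adjusted p = 0.00307), above background in 4 Y-27632 and 3 control channels, and the secreted WNT antagonist SFRP5 rose by 0.84 (adjusted p = 0.00545). The integrin subunit ITGB5, part of the receptor for shed outer segments, fell by 0.82 (limma, Benjamini-Hochberg adjusted p = 0.0102), the cadherin CDH3 fell by 0.54 (adjusted p = 0.0116), and PROS1, a ligand of phagocytic receptors chosen after its value was seen, was lower too. BEST1, a chloride channel of RPE, was above background in 2 channels of each group, with a change of 0.15 (SE 0.0855, limma, Benjamini-Hochberg adjusted p = 0.240). The list's mean was 0.35, with 0.05, 0.21, 0.75 and 0.39 on arrays 20, 21, 26 and 27, and under median centring it was -0.07, which is 0.33 above the median of all genes there (-0.41), where camera gave its lowest Benjamini-Hochberg adjusted p over the settings, 0.000232. With the main settings camera gave a Benjamini-Hochberg adjusted p of 0.0164, with adjusted p = 0.577 with an estimated correlation, and fry gave 0.112. The call was lost without enrichment 26, at a mean of 0.22 (camera, Benjamini-Hochberg adjusted p = 0.0904), and with all 8 channels above background, at 0.33 (0.121). The mean was 0.15 without background subtraction and 0.62 in the authors' values, and over the settings BEST1 ran from 0.03 to 0.78 and CDH3 from -1.10 to -0.29. RLBP1 missed the threshold without enrichments 21, 26 or 27 (1.65, 1.41 and 1.61, limma's Benjamini-Hochberg adjusted p = 0.0532, 0.0549 and 0.0832), ITGB5 missed it without 27 (-0.83, 0.0502), and ITGB5, SLC16A8 and CDH3 missed it without the block (0.115, 0.0571 and 0.0903). PROS1 missed it without 20, 21 or 27 (-0.49, -0.46 and -0.64, limma's Benjamini-Hochberg adjusted p = 0.104, 0.0797 and 0.0834). PROS1 was also not called without the block (0.541), with a random block (0.0872), with no filter (0.0633), as the mean of its probes (0.0983) and, like RLBP1, without background subtraction (-0.45 and 0.96, 0.0886 and 0.0663).

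Pigmentation genes went both ways: of 21 measured, 7 were higher, 3 lower and 11 not past the test, or 9 higher and 3 lower adjusted over the list alone. PMEL, the protein of melanosome fibrils, rose from 13.42 ± 0.88 to 14.65 ± 0.35 (SD, n = 4; log2 change 1.23, SE 0.268, limma, Benjamini-Hochberg adjusted p = 0.0204). The cation channel TRPM1 rose by 1.22 (SE 0.105, adjusted p = 0.00307 by limma with Benjamini-Hochberg adjustment), and MYRIP, a linker of melanosomes to myosin, rose by 0.32 (adjusted p = 0.0185), above background in 3 Y-27632 and 2 control channels. The melanosome motor MYO5A fell by 0.88 (limma, Benjamini-Hochberg adjusted p = 0.00650), RAB32, which directs enzymes to melanosomes, fell by 0.28 (adjusted p = 0.0305), and the melanocortin receptor MC1R, chosen after its value was seen, was also lower. RAB32 had another probe at 0.32, and the mean of its probes was 0.02, while that of MYO5A was -0.57. The list's mean was 0.35, with 0.01, 0.14, 0.74 and 0.51 on arrays 20, 21, 26 and 27, and it was not called by camera (Benjamini-Hochberg adjusted p = 0.113) or fry (0.112), with adjusted p = 0.577 with an estimated correlation. Under median centring the mean was -0.05, which is 0.35 above the median of all genes there (-0.41), and camera called the list (Benjamini-Hochberg adjusted p = 0.00577). Without enrichments 20, 21, 26 and 27 the mean was 0.46, 0.42, 0.22 and 0.30, and camera gave a Benjamini-Hochberg adjusted p of 0.0458, 0.0942, 0.189 and 0.187. The mean was 0.21 without background subtraction and 0.57 in the authors' values, and MYRIP ran from 0.06 to 1.41 over the settings. PMEL missed the threshold without enrichment 27 (1.29, limma's Benjamini-Hochberg adjusted p = 0.0733), without the block (0.0990), under quantile normalization (0.96, 0.0595) and in the authors' values (0.92, 0.0682). RAB32 missed it when any of the 4 enrichments was left out, at -0.32 to -0.24 and limma's Benjamini-Hochberg adjusted p from 0.0624 to 0.103, MYRIP without 20 (0.30, limma's Benjamini-Hochberg adjusted p = 0.0708) or 26 (0.30, 0.0664), and MYO5A, RAB32 and MYRIP without the block (0.0538, 0.0990 and 0.115). MC1R missed it when any of the 4 enrichments was left out (-0.46 to -0.26, limma's Benjamini-Hochberg adjusted p from 0.0561 to 0.113), without the block (0.0802), with no filter (0.0706), in the authors' values (0.0526) and, like MYRIP, without background subtraction (0.0900 and 0.0720). RAB32 missed it with net intensities, under quantile normalization, at the 75th percentile and in the authors' values (-0.20 to -0.17, 0.121 to 0.223). The means of both lists were largest on array 26, while array 27 had the fewest probes above background.

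Of 8 transcription factors of RPE and the eye field, 2 were higher, 0 were lower and 6 did not pass, also 2 and 0 adjusted over the list alone. RAX, which specifies the eye field, rose by 1.31 (SE 0.237, limma, Benjamini-Hochberg adjusted p = 0.0124), above background in 4 Y-27632 and 3 control channels. MITF, which drives pigment genes, rose by 0.43 (SE 0.102, limma, Benjamini-Hochberg adjusted p = 0.0251), but stood at -0.19 under median centring. The median of all genes was -0.41 there, and MITF, OTX2 and the mean of the list lay 0.22, 0.23 and 0.26 above it. OTX2 was at 0.08 (-0.17 under median centring; SE 0.0745, limma, Benjamini-Hochberg adjusted p = 0.429). The list's mean was 0.24, or -0.14 under median centring, and it was not called (camera, Benjamini-Hochberg adjusted p = 0.193, and fry, 0.152). It was 0.43 in the authors' values and 0.09 without background subtraction. MITF missed the threshold without enrichment 26 (0.35, limma's Benjamini-Hochberg adjusted p = 0.0781) or 27 (0.39, 0.10), and RAX without 27 (1.16, 0.0597). Both were lost without the block (0.114 and 0.0573) and without background subtraction (0.27 and 0.49, 0.0676 and 0.0553).

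**Figure D2:**
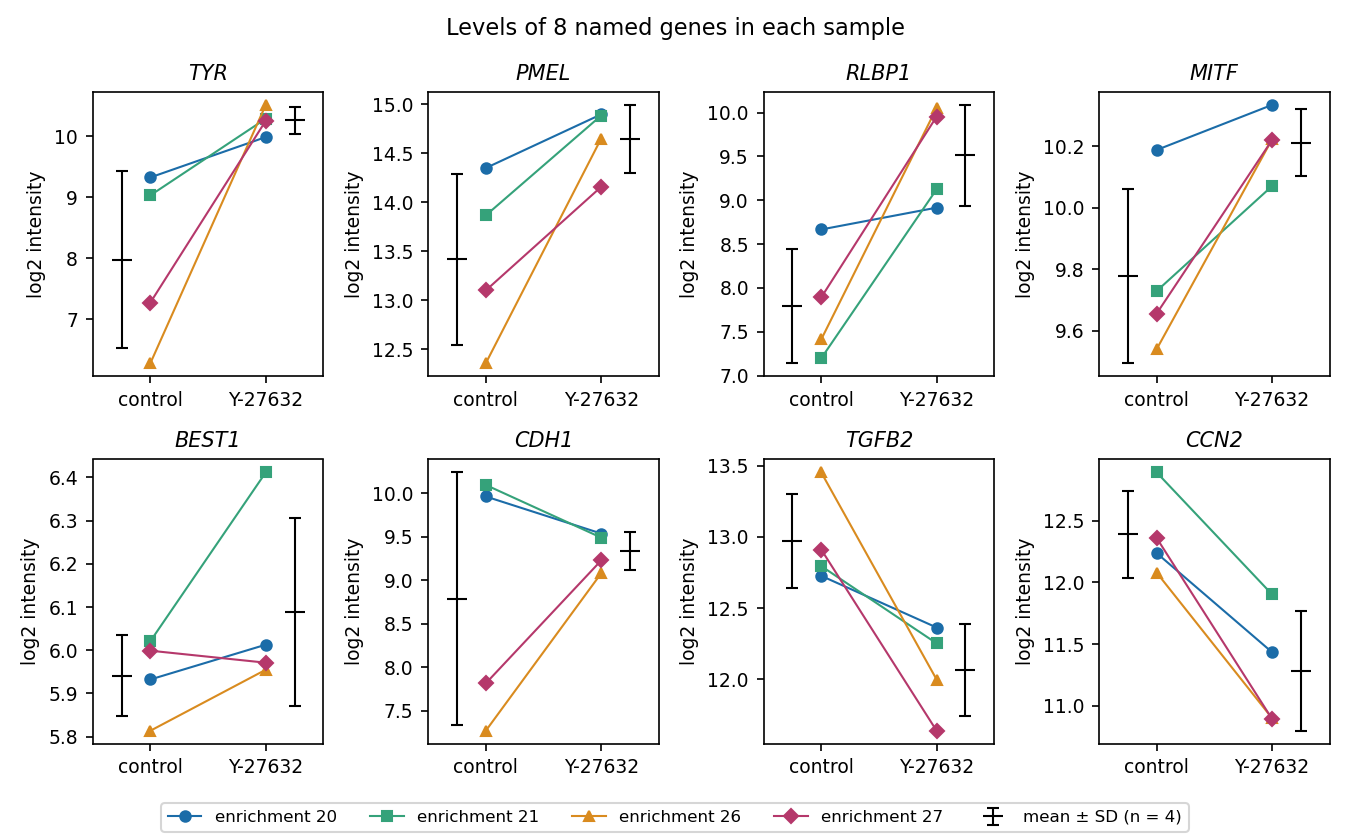
Normalized log2 intensity (y axis) of 8 genes in control and Y-27632 samples (x axis), with a line joining both samples of each enrichment and the mean ± SD (n = 4) in black. The control samples of TYR spread more (SD 1.45) than the Y-27632 samples (SD 0.22), CCN2 is lower with Y-27632 in each enrichment, and MITF, higher here by 0.43 on average, lies at -0.19 under median centring, as CDH1, not past the test at 0.55, lies at -0.04. The median of all genes is -0.41 there, and MITF and CDH1 lie 0.22 and 0.36 above it.

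Mesenchymal and matrix genes fell as a group. Of 27 measured, 17 were lower, 2 higher and 8 not past the test, with the same 2 and 17 adjusted over the list alone. Besides LOX, the cadherin CDH2 of mesenchymal cells fell by 1.23 (SE 0.0774, limma, Benjamini-Hochberg adjusted p = 0.00254), from 10.14 ± 0.25 to 8.92 ± 0.32 (SD, n = 4). The higher members were the intermediate filament gene VIM and the transcriptional repressor ZEB2. VIM rose by 0.30 (limma, Benjamini-Hochberg adjusted p = 0.0261), but was at -0.12 with net intensities, -0.16 under quantile normalization, -0.08 at the 75th percentile and -0.28 in the authors' values, so its direction depended on the scaling. ZEB2 rose by 0.30 (limma, Benjamini-Hochberg adjusted p = 0.0433). It had another probe at -0.09, and was at 0.09 as the mean of its probes (adjusted p = 0.271 by limma with Benjamini-Hochberg adjustment) and 0.02 under median centring (0.903). The smooth muscle actin ACTA2 was at 0.24 (-0.16 under median centring; SE 0.176, limma, Benjamini-Hochberg adjusted p = 0.338). The list's mean was -0.81 and lay at -0.54, -1.0, -0.85 and -0.86 on arrays 20, 21, 26 and 27. Camera gave a Benjamini-Hochberg adjusted p of 5.37e-05, with adjusted p = 0.577 with an estimated correlation, and fry gave 0.0200. VIM missed the threshold without enrichments 20, 21 or 27 (0.28, 0.26 and 0.31, limma's Benjamini-Hochberg adjusted p = 0.0974, 0.0623 and 0.0843), ZEB2 without 20, 21 or 26 (0.29, 0.26 and 0.27, adjusted p = 0.133, 0.107 and 0.133), and both without the block (0.167 and 0.25). VIM missed it under median centring (0.07, 0.591), with a trend (0.0620) and as the mean of its probes (0.0672), and ZEB2 without background subtraction (0.0865) and with no filter (0.0573). Without background subtraction the matrix mean was -0.54.

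Genes of TGF-beta and BMP signalling were lower more often than higher: of 37 measured, 18 were lower, 4 higher and 15 not past the test, or 22 lower and 4 higher adjusted over the list alone. The ligand gene TGFB2 fell by 0.91 (SE 0.197, limma, Benjamini-Hochberg adjusted p = 0.0201), the activin subunit INHBA fell by 1.30 (-1.96 as the mean of its probes; adjusted p = 0.00307) and the BMP antagonist GREM1 fell by 1.79 (adjusted p = 0.00338). The higher members were the ligands BMP7 (1.42, limma, Benjamini-Hochberg adjusted p = 0.00338, with another probe at -0.00 and the mean of its probes at 0.64) and BMP4 (0.97, adjusted p = 0.0138), the signal transducer SMAD3 (negative under median centring) and ID2, a BMP target, the last pair chosen after their values were seen. The mean was -0.29, with -0.27, -0.35, -0.22 and -0.32 on arrays 20, 21, 26 and 27. Camera gave a Benjamini-Hochberg adjusted p of 0.0134, with adjusted p = 0.577 with an estimated correlation, and fry gave 0.0176. Under median centring the mean was -0.73, which is -0.32 relative to all genes, and camera's Benjamini-Hochberg adjusted p was 0.173. TGFB2 missed the threshold without enrichment 26 (-0.73, limma's Benjamini-Hochberg adjusted p = 0.0544) or 27 (-0.79, 0.0852), BMP4 without 27 (0.99, 0.0600), and BMP4 and INHBA without the block (0.0915 and 0.169). SMAD3 missed it without 26 or 27 (0.41 and 0.40, limma's Benjamini-Hochberg adjusted p = 0.0660 and 0.0819), ID2 without 21, 26 or 27 (0.96, 0.58 and 0.80; 0.0648, 0.0758 and 0.140), with no filter (0.0873) and as the mean of its probes (0.0744), and both without the block (0.256 and 0.371). BMP4 and ID2 missed it under median centring (0.44 and 0.25; 0.0962 and 0.375). TGFB2, BMP4, SMAD3 and ID2 did without background subtraction (0.0646, 0.0666, 0.0635 and 0.0816), where the list's mean was -0.18.

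Targets of YAP and TAZ, the co-activators that respond to cell tension, were lower in 10 of 22 cases, higher in 2 and not past the test in 10, or 10 lower and 3 higher adjusted over the list alone. CCN2, a matrix-associated growth factor, fell by 1.11 (SE 0.115, limma, Benjamini-Hochberg adjusted p = 0.00380), from 12.39 ± 0.35 to 11.28 ± 0.48 (SD, n = 4), and the RNA-binding protein gene RBMS3 fell by 1.52 (-0.76 as the mean of its probes; adjusted p = 0.00307). The transcription factor FOXF2 rose by 0.74 (limma, Benjamini-Hochberg adjusted p = 0.0226), above background in 3 Y-27632 and 2 control channels, and the kinase NUAK2 rose by 0.35 (-0.19 under median centring; adjusted p = 0.0408). The mean of -0.39 was called by fry (Benjamini-Hochberg adjusted p = 0.0308) and not by camera (0.112), except without enrichment 21 (-0.43, 0.0346) and with the mean of a gene's probes (-0.33, 0.0463), against adjusted p = 0.577 with an estimated correlation. It was -0.92 under median centring, and FOXF2 ran from 0.17 to 2.15 over the settings. Without enrichment 20 or 21, limma's Benjamini-Hochberg adjusted p was 0.0642 or 0.0562 for FOXF2 (0.76 and 0.74) and 0.0711 or 0.103 for NUAK2 (0.40 and 0.29). NUAK2 also missed the threshold without 27 (0.28, limma's Benjamini-Hochberg adjusted p = 0.143), and FOXF2 and NUAK2 did without the block (0.0717 and 0.749), without background subtraction (0.0737 and 0.105) and with no filter (0.0502 and 0.0617), and NUAK2 with a random block (0.266).

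Actin and SRF target genes were lower in 8 of 30 cases, higher in 3 and not past the test in 19, with the same counts adjusted over the list alone. FHL2, a cofactor of SRF, fell by 1.97 (SE 0.227, limma, Benjamini-Hochberg adjusted p = 0.00459), and DSTN, which severs actin filaments, fell by 0.74 (adjusted p = 0.00374). The cytoplasmic actins ACTB (0.39, limma, Benjamini-Hochberg adjusted p = 0.0186) and ACTG1 (0.42, adjusted p = 0.0229) and the non-muscle myosin MYH10, chosen after its value was seen, were higher, but ACTB was at -0.05 under quantile normalization and -0.12 in the authors' values, and MYH10 was negative under median centring. Other probes of ACTB lay at -0.07, -0.05 and -0.18, and another probe of ACTG1 at -0.19. Both were at 0.01 to 0.15 with net intensities, at the 75th percentile, under median centring and as the mean of their probes (limma, Benjamini-Hochberg adjusted p from 0.230 to 0.938). ACTG1 was at 0.05 under quantile normalization (0.781) and 0.01 in the authors' values (0.945), so neither rise held under these settings. The list's mean was -0.17 and its median 0.05, and camera pointed down without a call (Benjamini-Hochberg adjusted p = 0.722), as did fry (0.377). Under median centring the list was at -0.64, and ROCK1 ran from -0.97 to -0.24 over the settings. ROCK1, a target of the inhibitor, fell by 0.37 (SE 0.0770, limma, Benjamini-Hochberg adjusted p = 0.0183), whereas ROCK2 was at 0.09 (-0.22 under median centring; SE 0.0634, adjusted p = 0.303). Calls were lost for ROCK1 without enrichment 26 (-0.30, limma's Benjamini-Hochberg adjusted p = 0.0595) or 27 (-0.36, 0.0748), ACTB without 20 (0.35, 0.0694) or 27 (0.40, 0.0708), ACTG1 without 27 (0.39, 0.0930), and ACTB without the block (0.0533). MYH10 missed it when any of the 4 enrichments was left out (0.23 to 0.37, limma's Benjamini-Hochberg adjusted p from 0.0613 to 0.0966), without the block (0.155), without background subtraction (0.118), with no filter (0.0581) and, like ROCK1, in the authors' values (0.0552 and 0.0518). Without enrichment 26 the mean of the list was -0.11.

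Genes of epithelial junctions and keratins were not called as a list, with 3 of 20 higher, 5 lower and 12 not past the test, and the same counts adjusted over the list alone. The tight junction genes CGN (0.43, or 0.27 as the mean of its probes and 0.11 under median centring, where it was not called; limma, Benjamini-Hochberg adjusted p = 0.00768) and TJP1 (0.25, or -0.37 under median centring and 0.12 as the mean of its probes; adjusted p = 0.0254) and the polarity gene PARD6B were higher. The tight junction gene CLDN1 fell by 0.45 (limma, Benjamini-Hochberg adjusted p = 0.00711), the desmosomal JUP fell by 0.46 (adjusted p = 0.00820), and the keratins KRT8 and KRT19 and the membrane linker EZR were lower, these and PARD6B being chosen after their values were seen. CDH1, the epithelial cadherin, was at 0.55 (-0.04 under median centring; SE 0.439, limma, Benjamini-Hochberg adjusted p = 0.382), with ratios of -0.43, -0.61, 1.81 and 1.41 on arrays 20, 21, 26 and 27. Under median centring CDH1 lay 0.36 above the median of all genes. The mean and median of the list were both 0.00, and camera pointed down without a call (Benjamini-Hochberg adjusted p = 0.963), as did fry (0.329). CLDN1 ran from -1.07 to -0.31 and JUP from -1.07 to -0.37 over the settings. The mean was -0.05 without enrichment 26, -0.03 without 27 and -0.38 under median centring. TJP1 missed the threshold when any of the 4 enrichments was left out (0.24 to 0.27, limma's Benjamini-Hochberg adjusted p from 0.0545 to 0.0910), and TJP1, CLDN1 and JUP missed it without the block (0.252, 0.170 and 0.106). KRT19 missed it when any of the 4 enrichments was left out (-0.34 to -0.21, limma's Benjamini-Hochberg adjusted p from 0.0641 to 0.128) and without background subtraction (-0.09, 0.562). EZR missed it without 20, 21 or 27 (-0.30, -0.28 and -0.37; 0.111, 0.0765 and 0.0819), PARD6B without 21, 26 or 27 (1.10, 0.75 and 0.76; 0.0509, 0.108 and 0.133) and KRT8 without 27 (-0.53, 0.0516). Without the block limma's Benjamini-Hochberg adjusted p was 0.467, 0.347, 0.0733 and 0.0847 for these 4 genes. EZR missed it also with net intensities, under quantile normalization, at the 75th percentile and in the authors' values (-0.27 to -0.24, 0.0908 to 0.146). EZR, KRT8 and TJP1 missed it as the mean of their probes (-0.11, -0.22 and 0.12; 0.615, 0.0900 and 0.198), and PARD6B under median centring (0.41, 0.165) and without background subtraction (0.45, 0.102). KRT19 missed it with a random block (0.0665) and with a trend (0.0678), KRT19 and PARD6B with no filter (0.0621 and 0.0822), and TJP1 in the authors' values (0.0522).

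Genes of hypoxia and glycolysis fell: of 19 measured, 13 were lower, 0 higher and 6 not past the test, or 15 lower adjusted over the list alone. The glycolytic enzyme gene PGK1 fell by 0.77 (SE 0.0755, limma, Benjamini-Hochberg adjusted p = 0.00346), but its other probes were at -0.09, -0.13 and -0.32 and the mean of its probes at -0.33. BNIP3, a mitochondrial protein induced by hypoxia, fell by 1.46 (SE 0.160, adjusted p = 0.00413 by limma with Benjamini-Hochberg adjustment). The mean was -0.54, with -0.48, -0.84, -0.36 and -0.49 on arrays 20, 21, 26 and 27. Camera gave a Benjamini-Hochberg adjusted p of 3.60e-05, with adjusted p = 0.577 with an estimated correlation, and fry gave 0.0295. The hypoxia and glycolysis list had a mean of -0.35 without background subtraction and -1.01 under median centring. PGK1 and BNIP3 missed the threshold without the block (limma, Benjamini-Hochberg adjusted p = 0.0552 and 0.119).

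**Figure D3:**
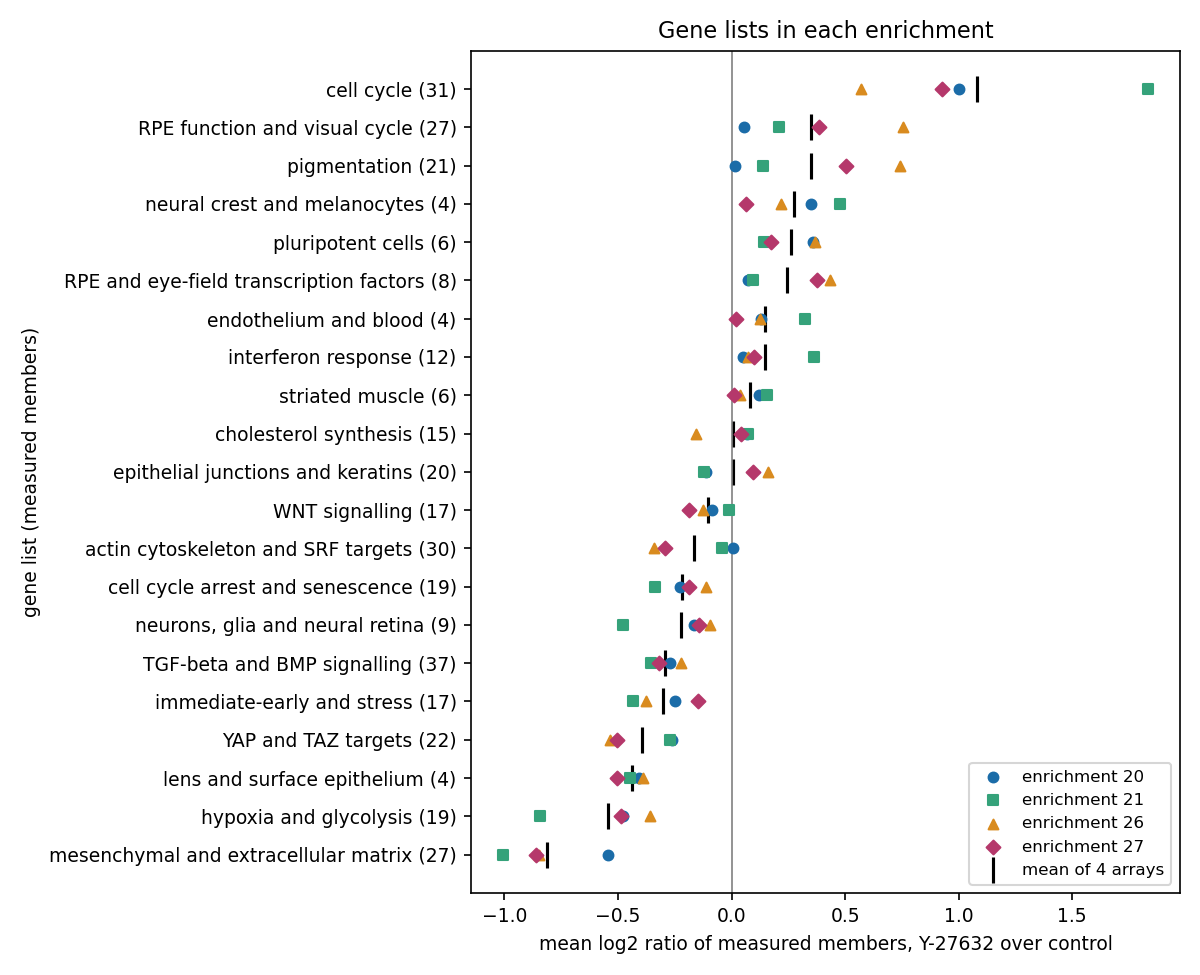
Mean log2 ratio of Y-27632 over control (x axis) of the measured members of 21 gene lists (y axis, number of members in brackets), with a symbol per enrichment and the mean of 4 arrays as a black bar. Cell cycle genes lie at 0.57 to 1.83 and matrix genes at -1.0 to -0.54, while the RPE function list, at 0.05 to 0.75, has a mean of -0.07 under median centring, and the pigmentation list one of -0.05, which lie 0.33 and 0.35 above the median of all genes there.

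The lists of markers of pluripotent cells, neurons, neural crest, lens, muscle and endothelium held 14, 22, 10, 15, 13 and 14 genes. Most genes of each list had no tested probe. Few of the measured markers of these other cell types changed, and camera called none of the 6 lists with the main settings. Fry called those of lens and surface epithelium (Benjamini-Hochberg adjusted p = 0.00887, lower), pluripotent cells (0.0389, higher) and neurons, glia and neural retina (0.0389, lower). It did not call those of neural crest, muscle and endothelium (0.112, 0.741 and 0.130). Under median centring camera called those of pluripotent cells, neural crest, muscle and endothelium (Benjamini-Hochberg adjusted p = 0.00577, 0.00146, 0.0353 and 0.0245). With the main settings camera gave these lists a Benjamini-Hochberg adjusted p = 0.577 with an estimated correlation, and 0.986 for muscle. Of 6 genes of pluripotent cells, 2 were higher, 0 lower and 4 not past the test (2 higher and 1 lower adjusted over the list alone), with a mean of 0.26 and a camera Benjamini-Hochberg adjusted p of 0.375. The DNA methyltransferase DNMT3B rose by 1.09 (SE 0.103, limma, Benjamini-Hochberg adjusted p = 0.00338), and SOX2, a transcription factor also of neural progenitors, rose by 0.82 (0.49 as the mean of its probes; adjusted p = 0.0372), above background in 3 channels of each group. Of 9 genes of neurons, glia and neural retina, 1 was lower and 8 did not pass, with a mean of -0.22, or -0.13 without enrichment 21 (camera, Benjamini-Hochberg adjusted p = 0.481), and the neuronal STMN2 fell by 0.72 (limma, Benjamini-Hochberg adjusted p = 0.00490). Of 4 genes of neural crest and melanocytes, 1 was higher, with a mean of 0.28 (camera, Benjamini-Hochberg adjusted p = 0.214), and the receptor KIT rose by 0.80 (limma, Benjamini-Hochberg adjusted p = 0.0116), above background in 4 Y-27632 channels and 1 control channel. Of 4 genes of lens and surface epithelium, 1 was lower, or 2 adjusted over the list alone, with a mean of -0.44 (camera, Benjamini-Hochberg adjusted p = 0.116), and the lens filament gene BFSP1 fell by 1.09 (limma, Benjamini-Hochberg adjusted p = 0.00269). Of 6 genes of striated muscle, 1 was higher, with a mean of 0.08 (-0.00 under median centring; camera, Benjamini-Hochberg adjusted p = 0.853), and the sarcomere gene TTN rose by 0.67 (limma, Benjamini-Hochberg adjusted p = 0.0244), above background in 3 Y-27632 channels and 1 control channel. Of 4 genes of endothelium and blood, 0 passed, with a mean of 0.15, or 0.09 without enrichment 21 (camera, Benjamini-Hochberg adjusted p = 0.375), TEK at 0.46 and VWF at 0.08 (limma, Benjamini-Hochberg adjusted p = 0.0733 and 0.343). Over the settings the means ran from 0.08 to 0.49 for pluripotent cells, -0.47 to -0.12 for neurons, 0.06 to 1.09 for neural crest, -0.89 to -0.15 for lens, -0.09 to 0.33 for muscle and -0.01 to 0.54 for endothelium. KIT ran from 0.17 without background subtraction to 2.88 in the authors' values. TTN ran from 0.14 to 2.54, SOX2 from 0.25 to 1.71, TEK from 0.11 to 1.2 and VWF from 0.01 to 0.42. The counts of the neuronal, neural crest, muscle and endothelial lists were the same adjusted over the list alone. SOX2 missed the threshold without enrichments 20, 21 or 26 (0.58, 0.94 and 0.74, limma's Benjamini-Hochberg adjusted p = 0.0837, 0.0531 and 0.113), and TTN without 20 or 26 (0.71 and 0.70, both 0.063). The threshold was missed by SOX2, STMN2 and TTN without the block (0.401, 0.663 and 0.0517), by STMN2 with a random block (0.145), by SOX2 and TTN with no filter (0.0808 and 0.0523), and by these 3 and KIT without background subtraction (0.101, 0.0762, 0.0988 and 0.0547). TEK passed with 5 other settings, such as net intensities (0.95, limma's Benjamini-Hochberg adjusted p = 0.0312), and VWF in the authors' values (0.42, 0.0330).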

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

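The tests of array quality, of the spread between control cultures and of brightness were chosen only after the result was seen, and the other tests were set beforehand.

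Dye and treatment divided the channels in the same way, so the 3850 changed genes may reflect a preference of single probes for one dye. Among 1678 called genes with a second tested probe, 80.8% of the second-brightest probes had the sign of the call (95% Wilson interval 78.9% to 82.6%), against 52.1% if both probes were independent and 59.7% among 3093 genes that were not called. At a change of at least 2-fold the share was 95.2% of 145 genes, which argues against bias of single probes as the whole cause. Probe sequences were not used, so second probes may overlap the first, and overlapping probes could share a bias. The second probe's change was 0.349 of the first's in the median, and 0.482 at 2-fold. The second probe is dimmer, where the offset shrinks a change, and genes were called on the first, so this ratio does not measure bias. Bias of single probes stays open as a part of the cause, as do a dye difference on all probes of a transcript and Y-27632 itself, and the design cannot separate them. Of 32 splits of the 8 channels that could be fitted with the block, 1, the real one, gave 3850 changed genes and the highest of the others gave 0, but 24 of them part only 2 pairs and leave the difference within the other pairs in the residual, so they are no like comparison, and the 8 that part all 4 pairs (1 as large, the highest other 0) are too few for a share under 0.05.

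The called-higher genes of RPE function and pigmentation rose more on arrays 26 and 27, which had the lowest shares of probes above background, with an excess of 0.45 over arrays 20 and 21 in 18 genes. Array quality was one possible explanation. In 10000 lists of other called-higher genes of like brightness the excess was -0.19 to 0.14 (middle 95%, median -0.02), and 0 were as large. Other genes of like brightness thus showed no such excess in general. The genes of these lists were drawn singly, and lists whose genes move together would spread more, so array quality is not excluded. The mean level of the 18 genes was 8.43, 8.22, 7.67 and 7.93 in the controls of enrichments 20, 21, 26 and 27 and 8.95, 9.06, 9.06 and 8.81 with Y-27632, an SD of 0.33 against 0.12. The controls of 26 and 27 were the lowest, while the Y-27632 levels lay close together, so the excess lay mainly in lower controls. Why these controls were lower was not tested. A larger spread between control cultures than between Y-27632 cultures was found in 61.1% of the 18 genes (exact 95% interval 35.7% to 82.7%), against 50.4% of all called-higher genes and 58.5% of all genes. With so few genes, this count of single genes does not decide the matter.

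Of 256 groups of 4 samples tested for a sample far from the others, 17 had one, where chance gives about 5%. Enrichment 27, which had the lowest share of probes above background, held 10 of them, enrichment 21 held 4, enrichment 26 held 3 and enrichment 20 held 0. In the Y-27632 sample of enrichment 27, log2 levels lay apart from the other Y-27632 samples for COL8A2 (9.67 against 10.33 to 10.44), ASPM (10.18 against 9.76 to 9.83), TJP1 (9.58 against 9.85 to 9.91), JUNB (10.27 against 9.63 to 9.66) and ROCK2 (7.16 against 6.79 to 6.80). In the control of enrichment 27, they lay apart for ZEB2 (7.0 against 6.44 to 6.5), TJP1 (9.30 against 9.61 to 9.64) and BMP7 (9.11 against 8.31 to 8.39). The mean level of a list lay apart in enrichment 27 for pigmentation (8.65 against 8.72) with Y-27632, and for striated muscle in the control (6.41 against 6.71 to 6.77). In enrichment 26, RAX (9.0 against 7.82 to 7.98) and GREM1 (6.86 against 7.30 to 7.36) with Y-27632 and CDKN2A in the control (9.22 against 10.03 to 10.11) lay apart. In enrichment 21, BEST1 (6.41 against 5.95 to 6.01) and the WNT list mean (8.40 against 8.16 to 8.19) with Y-27632, and SFRP5 (6.96 against 6.43 to 6.51) and ISG15 (8.77 against 9.35 to 9.42) in the control, lay apart.

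Control spots outside the comparison also gave signal above the 95th percentile of the negative control spots. Over the 8 channels the share was 16.7% to 24.3% for spots whose names begin with AT, 100% for bright corner spots and 25.7% to 47.5% for dark corner spots.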

How the results depend on the processing

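All alternatives were planned, and no test here was chosen only after the result was seen. Against 1606 higher and 2244 lower genes, counts beyond 1.5 times apart were 832 higher without background subtraction, 323 higher and 7082 lower under median centring, 403 and 689 at an adjusted p under 0.01, and 195 and 184 at 2-fold. Without the replicate block they were 380 and 562, all 942 being main calls. Leaving out an enrichment gave 583 to 1292 higher and 889 to 1788 lower genes, from fewer arrays. Every other setting stayed within 1.5 times. With an estimated correlation the calls were lost for RPE function (0.35), matrix (-0.81), TGF-beta (-0.29), cell cycle (1.08) and hypoxia and glycolysis (adjusted p = 0.577 each). That setting called no list, and its tied adjusted p does not rank the lists. With the other settings camera's adjusted p ranged from 0.000232 to 0.121 for RPE function, from 0.00577 to 0.238 for pigmentation, from 2.46e-07 to 0.0395 for matrix, from 0.00548 to 0.173 for TGF-beta, from 1.39e-22 to 2.04e-12 for cell cycle and from 9.87e-07 to 0.00229 for hypoxia and glycolysis. With all 8 channels above background, over fewer genes, RPE function was at 0.33, junctions at -0.014, muscle at -0.088 and endothelium at -0.0069, and without background subtraction junctions were at -0.039. Leaving out an enrichment placed RPE function at 0.22 to 0.45, pigmentation at 0.22 to 0.46, junctions at -0.047 to 0.047 and cholesterol synthesis at -0.016 to 0.061. Under median centring values were RPE function -0.074, pigmentation -0.054, transcription factors -0.14, junctions -0.38, TGF-beta -0.73, interferon -0.19, cholesterol synthesis -0.49 and muscle -0.0031. Relative to the median of all genes these are 0.33, 0.35, 0.26, 0.03, -0.32, 0.22, -0.09 and 0.40. Single genes under median centring were MITF -0.19, TJP1 -0.37, NUAK2 -0.19, CYP51A1 -0.15, ZFP36 -0.069, OTX2 -0.17, CDH1 -0.041, ACTA2 -0.16, ROCK2 -0.22, SMAD3 -0.18, MYH10 -0.28 and USP18 -0.090, each 0.03 to 0.36 above that median. VIM was at -0.12 with net intensities, -0.16 under quantile normalization, -0.085 at the 75th percentile and -0.28 in the authors' values, ACTB at -0.053 under quantile normalization and -0.12 in the authors' values, and RAB32 at 0.022 as the mean of its probes. For changed results other than those from fewer arrays or genes, the cause was not tested. Of 104 named genes tested, 96 passed, of which 43 lost the call without an enrichment, 48 without the block and 44 under another background, scaling or the authors' values. Over all settings limma's Benjamini-Hochberg adjusted p reached from 0.00803 to 0.118 for TYR, 0.00358 to 0.0832 for RLBP1, 0.00714 to 0.0990 for PMEL, 0.00854 to 0.166 for MITF and 0.00215 to 0.0852 for TGFB2. Leaving out the block ended no list call of camera and added the immediate-early list (-0.30, adjusted p = 0.0367). The share of probes above the negative control spots, lowest on array 27, limits dim genes such as BEST1, AURKB and RPE65.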

Other observations

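The test of brightness for the hypoxia and glycolysis list was chosen only after the result was seen, and the test of its second probes was set beforehand.

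Genes of cell cycle arrest and senescence included opposed inhibitors. Of 19 measured, 5 were lower, 2 higher and 12 not past the test, with the same counts adjusted over the list alone, and a mean of -0.22 (camera, Benjamini-Hochberg adjusted p = 0.368; fry, 0.0389). Besides CDKN2B, its neighbour in function CDKN2A fell by 0.73 (SE 0.160, limma, Benjamini-Hochberg adjusted p = 0.0206), while CDKN1B rose by 0.66 (SE 0.0718, adjusted p = 0.00412) and CDKN1C by 0.68 (SE 0.198, adjusted p = 0.0458). As the mean of their probes these 3 genes were at -1.46, 0.40 and 0.36, the last not called (limma, Benjamini-Hochberg adjusted p = 0.0533), and under median centring CDKN1B and CDKN1C were at 0.14 and 0.17 without a call (0.185 and 0.437). The other lower members, chosen after their values were seen, were the lysosomal galactosidase GLB1, the secreted IGFBP7 and MDM2, which degrades p53. CDKN2A missed the threshold without enrichment 20 (-0.69, limma's Benjamini-Hochberg adjusted p = 0.0692) or 27 (-0.80, 0.0655), CDKN1C without 21, 26 or 27 (0.72, 0.48 and 0.62; 0.0900, 0.114 and 0.155), and both without the block (0.102 and 0.304). CDKN1C missed it without background subtraction (0.102) and with no filter (0.0940). GLB1 and IGFBP7 missed it without 20 (-0.38 and -0.55, limma's Benjamini-Hochberg adjusted p = 0.0750 and 0.0669) or 27 (-0.44 and -0.59, 0.0580 and 0.0655), MDM2 without 21, 26 or 27 (-0.36, -0.28 and -0.32; 0.0770, 0.120 and 0.134), and these 3 without the block (0.303, 0.749 and 0.462). IGFBP7 and MDM2 missed it with a random block (limma's Benjamini-Hochberg adjusted p = 0.258 and 0.0622) and without background subtraction (0.0845 and 0.0739). GLB1 and MDM2 missed it in the authors' values (0.0687 and 0.0594), MDM2 with no filter (0.0593) and GLB1 as the mean of its probes (-0.25, 0.0660). Immediate-early and stress genes were lower in 8 of 17 cases, higher in 2 and not past the test in 7, or 10 lower and 2 higher adjusted over the list alone, with a mean of -0.30 (camera, Benjamini-Hochberg adjusted p = 0.0751; fry, 0.0389). Camera called it without enrichment 27 (-0.35, Benjamini-Hochberg adjusted p = 0.0214), with no filter (0.0458), without the block and with a random block (0.0367 each) and as the mean of a gene's probes (-0.27, 0.0495), against adjusted p = 0.577 with an estimated correlation. Under median centring this list was at -0.75 and that of arrest and senescence at -0.71, and PPP1R15A ran from 0.11 to 1.15 over the settings. The transcription factor JUNB fell by 1.05 (SE 0.142, limma, Benjamini-Hochberg adjusted p = 0.00622; another probe was at 0.13, and the mean of its probes at -0.46) and IER3, an inhibitor of cell death, fell by 0.84 (adjusted p = 0.00586). PPP1R15A, a phosphatase subunit of the stress response, rose by 0.48 (limma, Benjamini-Hochberg adjusted p = 0.0216) and ZFP36, which destabilises mRNA, by 0.30 (-0.07 under median centring; adjusted p = 0.0211). PPP1R15A missed the threshold without 26 or 27 (0.47 and 0.38, limma's Benjamini-Hochberg adjusted p = 0.0688 and 0.0756), ZFP36 without 20, 26 or 27 (0.33, 0.31 and 0.29; 0.0543, 0.0590 and 0.0819), and both without the block (0.116 and 0.338). PPP1R15A missed it without background subtraction (0.0762).

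WNT signalling genes moved apart: of 17, 3 were higher, 5 lower and 9 not past the test, or 5 and 5 adjusted over the list alone. The secreted antagonist SFRP1 rose by 1.5 (SE 0.226, limma, Benjamini-Hochberg adjusted p = 0.00782) and the membrane inhibitor APCDD1 by 1.32 (adjusted p = 0.00499), above background in 4 Y-27632 and 3 control channels, while DKK3 fell by 1.07 (adjusted p = 0.00273) and the receptor FZD7 fell by 0.85 (adjusted p = 0.00338). The receptor FZD4 was also higher, and WNT5A, the ligand WNT5B and the receptor FZD8 lower, with FZD4, WNT5B and FZD8 chosen after their values were seen. The mean was -0.10 and the median 0.01, and camera pointed down without a call (Benjamini-Hochberg adjusted p = 0.995), while fry gave 0.0225. Over the settings the mean ran from -0.45 to -0.03 and APCDD1 from 0.36 to 2.84. FZD4 was at 0.35 as the mean of its probes and missed the threshold without 27 (0.72, limma's Benjamini-Hochberg adjusted p = 0.0605) and under median centring (0.13, 0.506). FZD8 missed it without 20 or 27 (-0.59 and -0.55; 0.0696 and 0.102), without the block (0.153) and with no filter (0.0632), and FZD4 and FZD8 missed it without background subtraction (0.0543 and 0.131). Of 12 interferon response genes, 3 were higher, 2 lower and 7 not past the test, or 4 and 2 adjusted over the list alone, with a mean of 0.15 (-0.19 under median centring and 0.07 without enrichment 21; camera, Benjamini-Hochberg adjusted p = 0.214; fry, 0.223). IFI27 (0.67, limma, Benjamini-Hochberg adjusted p = 0.00881), IFITM1 (0.74, adjusted p = 0.0274) and USP18, the last chosen after its value was seen and negative under median centring, were higher, and the ubiquitin-like ISG15 (-0.53, adjusted p = 0.0314) and the RNA sensor RIGI (-0.42, adjusted p = 0.0355) lower, RIGI above background in 3 Y-27632 and 4 control channels. IFITM1 missed the threshold without 20 or 27 (0.71 and 0.88, limma's Benjamini-Hochberg adjusted p = 0.0856 and 0.0507), ISG15 without 20, 26 or 27 (-0.57, -0.44 and -0.43; 0.0731, 0.10 and 0.117), RIGI without 20, 26 or 27 (-0.40, -0.31 and -0.46; 0.112, 0.0930 and 0.0929), and all of these without the block (0.241, 0.10 and 0.121). USP18 missed it when any of the 4 enrichments was left out (0.32 to 0.54, limma's Benjamini-Hochberg adjusted p from 0.0545 to 0.104) and without the block (0.102). IFI27 and IFITM1 missed it under median centring (0.26 and 0.17; 0.0692 and 0.546), and ISG15 in the authors' values (0.0508). IFITM1, ISG15, RIGI and USP18 missed it without background subtraction (limma's Benjamini-Hochberg adjusted p = 0.116, 0.0610, 0.102 and 0.0938) and with no filter (0.0594, 0.0615, 0.0616 and 0.0613). Over the settings the interferon mean ran from -0.19 to 0.25, ISG15 from -1.15 to -0.36 and RIGI from -1.19 to -0.09. Of 15 cholesterol synthesis genes, 1 was higher, 0 lower and 14 not past the test, the same adjusted over the list alone, with a mean of 0.01, a median of -0.00, a mean of -0.49 under median centring, -0.01, -0.02 and -0.01 without enrichments 20, 21 and 27, and no call (camera, Benjamini-Hochberg adjusted p = 0.812; fry, 0.832). The member was CYP51A1, a sterol demethylase, at 0.42 (-0.15 under median centring, another probe at -0.15; limma, Benjamini-Hochberg adjusted p = 0.0117, 0.548 without the block, 0.0751 with a random block and 0.191 as the mean of its probes, at 0.14).

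The lower level of the hypoxia and glycolysis list, with a mean of -0.54, may have a technical source, since many of its members are bright and a dye difference at high brightness can outlast loess. The middle 95% of 10000 lists matched on brightness lay at -0.26 to 0.13 and the lowest at -0.44, which argues against brightness as the whole source. The genes of these lists were drawn singly, however, and lists whose genes move together would spread more. Among 8 of its called genes with a second tested probe, 87.5% (7 of 8, exact 95% interval 47.3% to 99.7%) of second probes were lower, too few genes to exclude bias of single probes.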
